A study of Homo sapiens with 2 samples.

How the data were processed

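The samples were AGS cells, an established gastric adenocarcinoma line. One group was given 100 nM LBH589 for 24 h and the other was the control, each measured on 1 array. Groups, dose and time were taken from the submitters' labels. Per the labels' protocols, total RNA was extracted on silica columns and labelled with biotin by the manufacturer's 1-cycle method, which makes each array a 1-colour measurement. The array model and genome build are not given in the sources used here.

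The deposited values of each array were an intensity (signal) per probe set on a linear scale, as the values themselves show, for 33297 probe sets with numeric identifiers. MAS5 is named per the submitters' processing notes, with no version. Per the file headers, however, the signals of the deposited comparison table came from a gene-level RMA summary with default settings. Those sources differ. The fold of that table equalled the ratio of the deposited signals, as given below, which argues against MAS5 as the source of the deposited values. The signal columns of that table were not compared with them, so the method was not settled beyond this. Either method subtracts background in its own way, so ratios of dim probe sets depend on it. RMA in addition normalizes the arrays to each other by quantiles, and a shift shared by most genes would then be removed from the ratios. No detection calls were used here, and the probe sets carried no identifiers of control probes, so that 3' to 5' ratios and spike-in ratios were not analysed here. The authors' deposited comparison table also gave a fold (ratio of treated over control signal), which equalled the ratio of the deposited signals with a largest relative difference of 9.89e-09. The 2 further per-sample signal columns of that table were not used.

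From these values, log2 of treated minus log2 of control was computed per probe set. An array's 50th percentile (its median) was its detection limit, and 16648 probe sets were detected on each array. A probe set entered if detected on at least 1 array, and values below the 25th percentile of an array were set to it (3.08 on the treated array and 3.12 on the control array). A difference counted by size alone, at 2-fold or more, which is 1 on the log2 scale. Where a gene was detected on 1 array only, a bound was computed as its signal over the other array's detection limit and written as at least N-fold. Counts of differences and list medians used the measured value or the floor for an undetected signal, which can exceed the bound, and the counts with undetected values at the detection limit were computed beside them. Where these counts differ for a list, both are given. Genes were detected on both arrays in 11541 cases, on the treated array alone in 667 and on the control array alone in 506, and the bound reached 2-fold for 61 and 33 of the latter groups.

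Gene names came from the deposited annotation, updated with a RefSeq gene table of the human assembly GRCh38.p14, which was used only for names and for which genes neighbour each other. Of the probe sets, 18273 were matched by accession, 1137 by current symbol and 1045 by an older symbol, 1488 kept the file's symbol, 120 carried several symbols and were left unnamed, 6806 had an annotation without a symbol and 4428 had none. Several names were updated: PMEL stood as SILV, TENM3 as ODZ3, FBXW10B as CDRT1, USP17L2 as DUB3 and USP17L6P as DUB4. A gene was represented by its brightest detected probe set. Probe sets of near-identical genes may share targets, and 1171 probe sets had the same values on both arrays as another probe set.

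The spread available was that between probe sets of 1 gene on the same arrays, not between cultures. Over 526 genes with at least 2 distinct detected probe sets the SD was 0.29 on the log2 scale, and in 81.4% of those genes all probe sets had the same sign. Of 66 such genes at least 2-fold apart between arrays, 61 (92.4%) had the same sign on all probe sets.

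Genes named in the report followed a rule set before the data were examined. They were CITED2, the histone deacetylases and CDKN1A, then the 12 genes with the largest difference each way among genes detected on both arrays whose probe sets had the same sign, then the 5 each way with the largest bound among genes detected on 1 array. Genes without an official symbol and sex-linked marker genes were left out. Of each list the up to 4 detected members with the largest absolute ratio were named, with the most opposite member where one was needed. Some genes that this rule names are not reported here. RPL4, NPM1 and the genes named in the closing observations were picked after their values were seen. TOP2B and the undetected drug exporters ABCB1, ABCC2 and ABCG2 were also named outside this rule.

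The 32 gene lists held 786 members, 779 of them on the array and 656 detected. The median log2 ratio of each list was placed among 10000 random lists of the same size, drawn from 20 bins of mean log2 signal, and a list stood apart below the 2.5th or above the 97.5th percentile. Further lists, chosen after the values were seen, appear only in the closing observations.

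The calculation was tested on simulated data made from the signals of LBH589 against control, with a noise SD of 0.3 on the log2 scale. Of 17372 unchanged probe sets 0.0863% were called. This share follows from the simulated noise, which was independent between probe sets and alike at every signal level. The spread between cultures was not known, so the share does not give a rate of false calls in these data. Of 25 probe sets each, changes of 1.5-fold were called in 8% (higher) and 4% (lower), of 2.5-fold in 88% and 80%, of 4-fold in 100% and 84%, and of 8-fold in 100% and 92%. Of 200 lists of randomly drawn genes without a shift 5.5% stood apart, and 100% of these lists shifted by -0.5 did. Genes of such lists do not differ together as those of a real list can.

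Alternatives set before the data were examined were quantile normalization, centring on the detected median or on housekeeping genes, removal of a loess trend (span 0.4), no filter, detection on both arrays, an offset of 32 added to the signals, the authors' fold, the mean of a gene's probe sets, and a 3-fold size. Chosen after seeing the data were detection above the 75th percentile, undetected values at the detection limit, and leaving out probe sets with the same values. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.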

Results

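Gene expression was measured in AGS, an established human gastric adenocarcinoma cell line, with and without LBH589. LBH589 (panobinostat) is a hydroxamate that inhibits histone deacetylases, the enzymes that take acetyl groups off histones and other proteins. The data were 1 array of cells kept in 100 nM LBH589 for 24 h and 1 array of control cells, 2 arrays in all. The labels of the control differ, 1 calling it treated and another giving no treatment, so whether its cells received the drug's solvent stayed open. Each array carried signals for 33297 probe sets. The comparison addresses which transcripts stand at another level after exposure to the drug, and what is known of the study points in particular to CITED2, a transcriptional coregulator that binds the acetyltransferases CREBBP and EP300. With 1 array per group there is no replicate check on any difference given here, so no test of a difference between the conditions was run, no p-value is given and the number of arrays limits the precision.

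The 2 arrays were on a similar scale, which normalization by quantiles would by itself produce. The median signal was 4.77 on the treated array and 4.84 on the control array, the 75th percentiles were 21.9 and 22.3, and the brightest probe sets read 7375 and 7427. The log2 signals of the arrays correlated with a Pearson's r of 0.965 across probe sets, which are not independent replicates. Of 25 housekeeping genes, 24 were within 2-fold, with a median log2 ratio of treated over control of -0.08, at the 15.6th percentile of random gene lists matched on signal. REEP5, a protein of the endoplasmic reticulum membrane, was the exception at 154 on the control array and 76.8 on the treated array, and SDHA, a subunit of mitochondrial complex II, was 1.78-fold higher. Among housekeeping genes, POLR2A was 1.57-fold lower and PSMB2 1.51-fold lower. All 41 detected cytosolic ribosomal protein genes lay within 2-fold, with a median log2 ratio of 0.07 at the 47.1th percentile. RPL18 was 1.46-fold and RPS13 1.40-fold higher, while RPL22, detected on the control array alone, was at least 1.34-fold lower. RPL4 and NPM1, which proliferating cells express strongly, had signals of 3.33 to 3.58 and 3.25 to 3.45 on the 2 arrays, below the detection limit, so a probe set at background did not show that its gene was silent.

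TXNIP, an arrestin-like protein that binds thioredoxin and limits glucose uptake, read 32.9 on the control array and 2153 on the treated array, 65.4-fold higher, and its relative ARRDC4 was 27.5-fold higher, from 12.8 to 353. At the other end FPR3, a formyl peptide receptor, was 34.3-fold lower on the treated array, 16.9 against 581, ANXA3, a calcium-dependent phospholipid-binding annexin, was 27.4-fold lower, and TYMS, the thymidylate synthase that makes a precursor of DNA, was 17.8-fold lower, 10.2 against 181. CITED2 was 13.2-fold higher, with a signal of 30.5 on the control array and 404 on the treated array.

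Differences of at least 2-fold were about as common in either direction on the scale of the deposited values, 50.2% of gene calls being higher, but 58.3% were higher with the ratios centred on housekeeping genes. Of 12714 detected genes, 920 (7.24%) were at least 2-fold higher on the treated array, 913 (7.18%) were at least 2-fold lower and 10881 lay within 2-fold. With undetected values at the detection limit, so that such genes count only by their bound, 874 were higher and 891 lower. At 3-fold the counts were 272 higher and 326 lower. Of 17726 detected probe sets, 1122 were at least 2-fold higher and 1340 at least 2-fold lower. Probe sets without any annotation made up 133 of the higher and 357 of the lower ones. In the authors' deposited table, which also covers probe sets not detected here, 1145 probe sets had a fold change of at least 2 and 1380 a fold change of at most 0.5, and the values ran from 0.0292 to 174. The median log2 ratio over all detected genes was 0.01. Adding an offset of 32 to the signals reduced the calls to 208 genes higher and 224 lower. It pulls all ratios towards 0, those of dim genes most, and was larger than the 75th percentile of signal on either array.

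**Figure D1:**
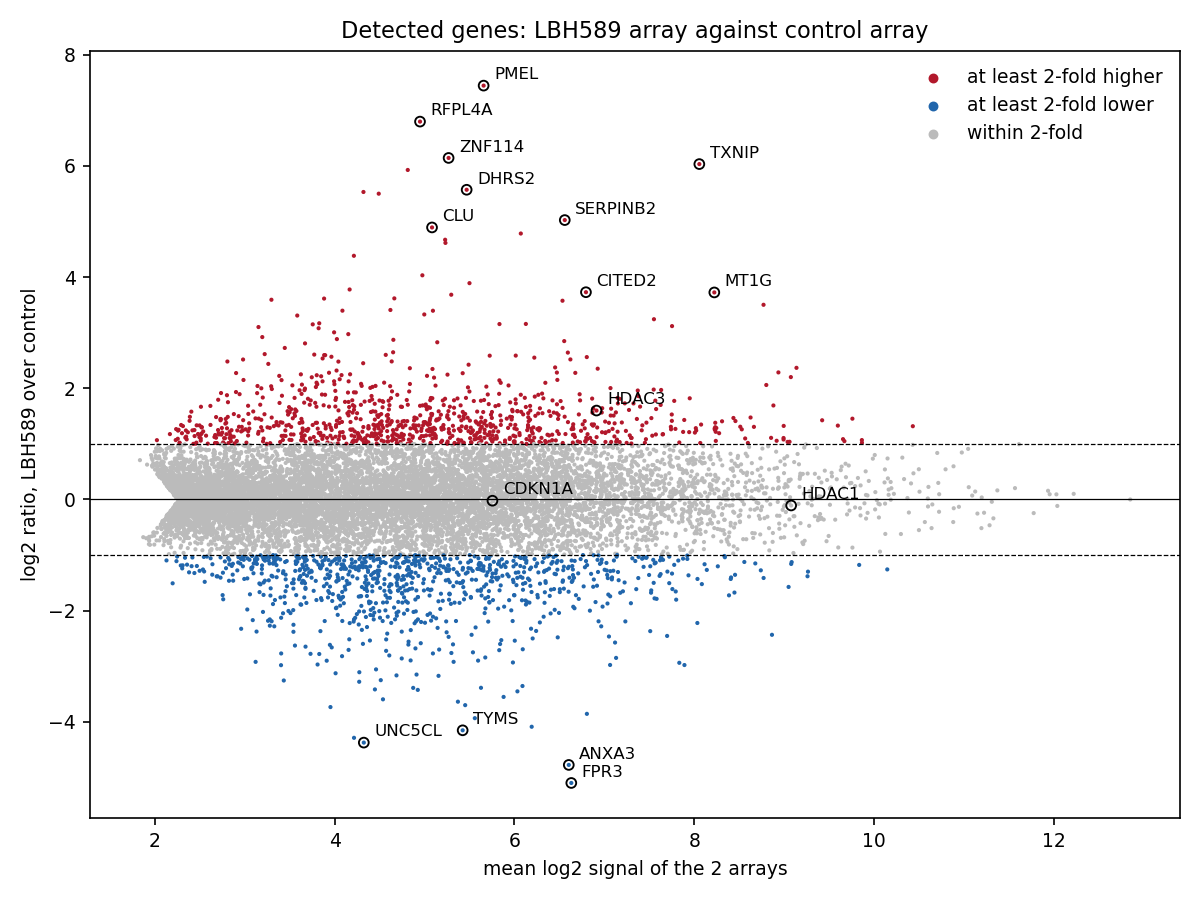
Log2 ratio of the LBH589 array over the control array for each of the 12714 detected genes (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis). Red points are the 920 genes at least 2-fold higher, blue points the 913 genes at least 2-fold lower, grey points the rest, dashed lines mark 2-fold, and circles mark named genes. A gene undetected on 1 array is drawn at its signal or floor there, beyond its bound. TXNIP lies at a log2 ratio of 6.03 and CDKN1A at -0.02.

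The 12 genes with the largest higher values among those detected on both arrays included TXNIP, ARRDC4 and CITED2. Also among them, DHRS2, a short-chain dehydrogenase, was 47.5-fold higher, from 6.43 to 305. SERPINB2, an inhibitor of plasminogen activators, was 32.6-fold higher and reached 538. CLU, the secreted chaperone clusterin, was 29.7-fold higher, and HSPA2, a heat shock protein of high level in testis, was 24.5-fold higher. ALDOC, the aldolase isoform typical of brain, was 25.5-fold higher. NR4A1, an orphan nuclear receptor and immediate early gene, was 16.4-fold higher, and CPA4, a metallocarboxypeptidase, was 14.8-fold higher. The metallothionein MT1G was 13.2-fold higher on its brighter probe set, with log2 ratios of 2.29 and 3.72 on its 2 probe sets. USP17, a deubiquitinase family of near-identical copies, was 13.7-fold higher on its brightest probe set, whose control signal of 4.85 lay next to the detection limit of 4.84. Of its 9 probe sets, which held 3 distinct sets of values, 2 were detected on the control array, so that the size for the family is close to a bound.

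A further group was detected on the treated array alone, so that each ratio is a lower bound set by the control array's detection limit. PMEL, the structural protein of melanosomes, read 666 on the treated array and was at least 138-fold higher. RFPL4A was at least 71.7-fold higher, and the zinc finger gene ZNF114 was at least 66.9-fold higher. USP17L2 and USP17L6P, members of the same deubiquitinase family as USP17, were at least 45.3-fold and at least 31.3-fold higher. Their sequences are close to each other's, so these values are not independent.

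On the lower side, the 12 leading genes included FPR3, ANXA3 and TYMS. SERPINH1, the collagen chaperone of the endoplasmic reticulum, was 15.3-fold lower on the treated array, 12.1 against 184, and RCN1, a calcium-binding protein of the same compartment, was 14.5-fold lower. MMP14, a membrane-bound metalloproteinase that cleaves collagen, was 13.0-fold lower. AMIGO2, an adhesion protein, was 17.0-fold lower, and TENM3, a teneurin, was 12.4-fold lower. SLC35D1, a nucleotide sugar transporter, was 12.1-fold lower and GALNT5, which starts mucin-type O-glycosylation, was 10.7-fold lower. TRIM16 and its partial copy TRIM16L were 10.9-fold and 11.7-fold lower, and cross-hybridisation between the pair cannot be excluded. Detected on the control array alone were UNC5CL, at least 19.1-fold lower, BCL2L15, a BCL2 family member, at least 17.2-fold lower, DNAJC15, a mitochondrial co-chaperone, at least 7.01-fold lower, and FGA, the fibrinogen alpha chain, at least 6.23-fold lower. FBXW10B was at least 11.8-fold lower on its brightest probe set, detected on the control array alone. Of its 3 detected probe sets 1 was detected on both arrays, at 11.3 and 4.94, a log2 ratio of -1.20.

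**Figure D2:**
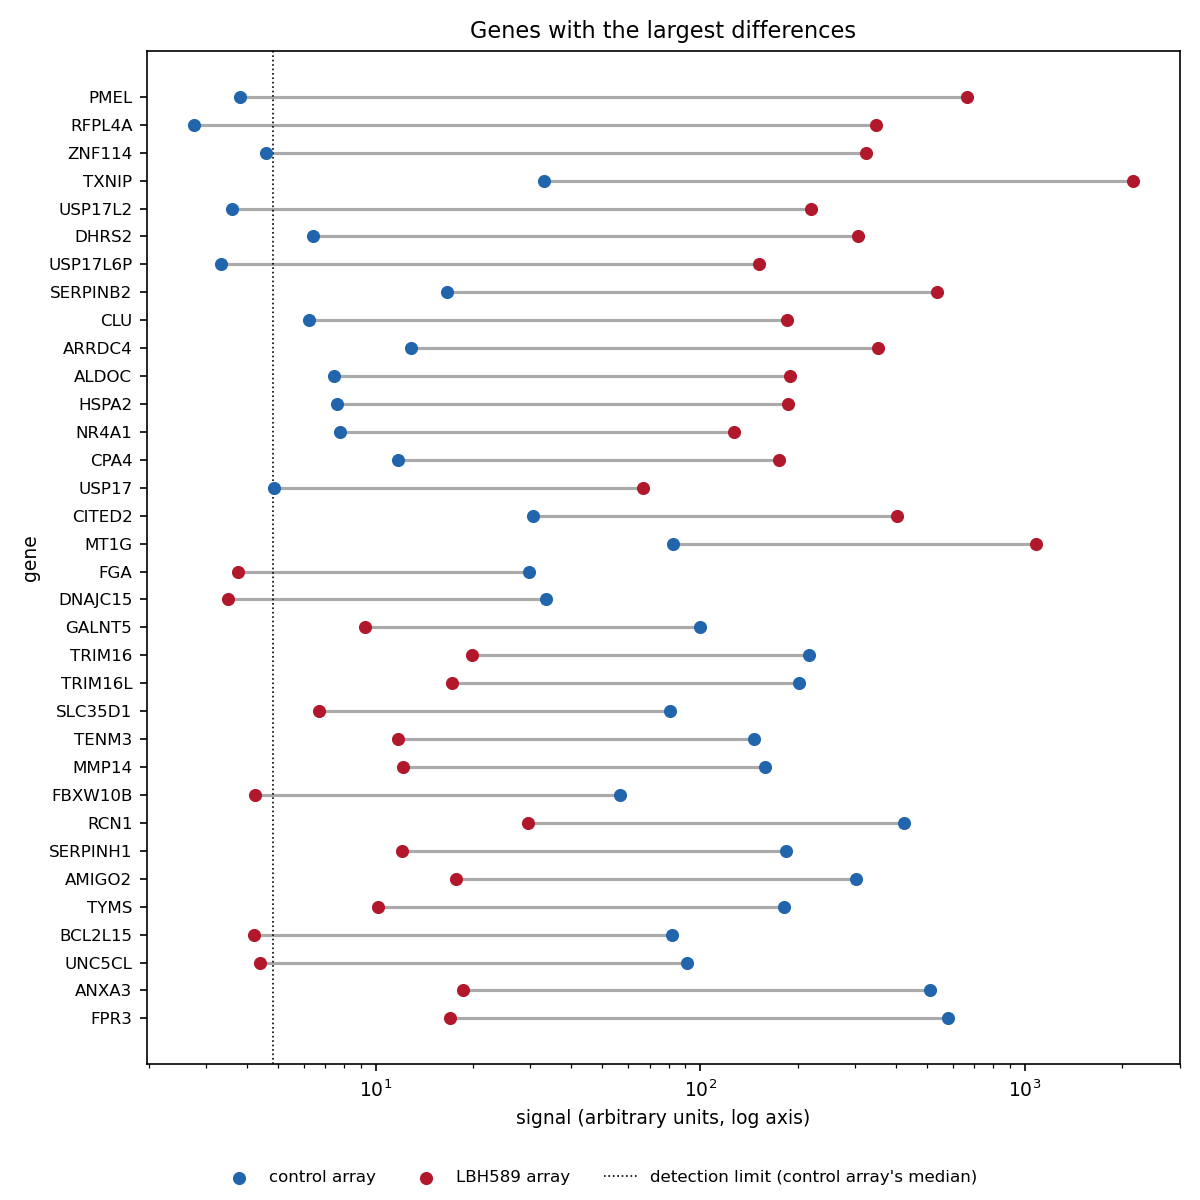
Signal on the control array (blue) and on the LBH589 array (red), in arbitrary units on a log axis, for the 12 genes with the largest difference each way among genes detected on both arrays and the 5 each way with the largest bound among genes detected on 1 array. The dotted line is the control array's median of 4.84, its detection limit, and TXNIP spans the range from 32.9 to 2153.

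Transcripts of the drug's targets were mostly within 2-fold. Of 10 detected histone deacetylases, HDAC3, the catalytic subunit of the NCOR corepressor complexes, was 3.03-fold higher, from 69.2 to 210, and HDAC7, of class IIa, was 2.34-fold lower, from 21.9 to 9.35. HDAC1 and HDAC2, the main nuclear class I enzymes, read 561 and 179 on the control array and had log2 ratios of -0.11 and -0.15. HDAC5 was 1.66-fold, HDAC4 1.63-fold and HDAC11 1.52-fold higher, and the log2 ratios of HDAC6, HDAC8 and HDAC10 were -0.08, 0.12 and 0.15. On the control array HDAC4 read 4.85, next to the detection limit of 4.84, and HDAC11 read 5.90, so both folds rest on dim signals. HDAC9 was not detected. The median log2 ratio of the family was 0.13, at the 73.8th percentile of random lists. Of the 6 detected members of a list of CITED2 and its partners, 5 had ratios below 0, with a median log2 ratio of -0.32 at the 9.16th percentile. CREBBP was 2.74-fold lower, SMAD3 was 1.89-fold lower and EP300 1.34-fold lower.

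Gene lists chosen before the data were examined were then set against 10000 random lists of the same size and signal level. Of 32 lists, 11 had a median outside the central 95% of the random medians, 9 lower and 2 higher. For lists of unrelated genes 1.6 are expected. Genes of 1 list can differ together between any 2 cultures and lists share members, so the number standing apart without the drug is unknown. The percentiles describe these 2 arrays only. With the offset of 32 the medians of all 11 lists were nearer 0 by over 1.5 times, from -0.62 for mitotic genes to 0.69 for genes reported to be higher with such drugs. Genes reported to be higher after histone deacetylase inhibition in other cells stood apart most on the higher side, with a median log2 ratio of 1.04 at the 100th percentile, 13 of 25 members at least 2-fold higher and 1 lower. Its leading members were TXNIP, DHRS2, CLU and CPA4, given above, and the member lower was the histone gene H2BC12 at 2.04-fold. The log2 ratio of H2BC12 was 0.03 where the mean of its probe sets was taken. CDKN1A, the CDK inhibitor often named as a marker of these drugs, was at 54.5 on the control array and 53.6 on the treated array, a log2 ratio of -0.02. Metallothioneins, metal-binding proteins encoded by near-identical copies, had a median log2 ratio of 0.64 at the 99.8th percentile, and 4 of 10 were at least 2-fold higher with none lower. MT1X was 11.9-fold, MT2A 11.3-fold and MT1F 2.39-fold higher, besides MT1G, while MT3 was 1.05-fold lower. MT1X and MT2A belong to both lists. The median of the metallothioneins was 0.14 with the offset of 32 and 3.54 over the 4 members above the 75th percentile of signal.

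**Figure D3:**
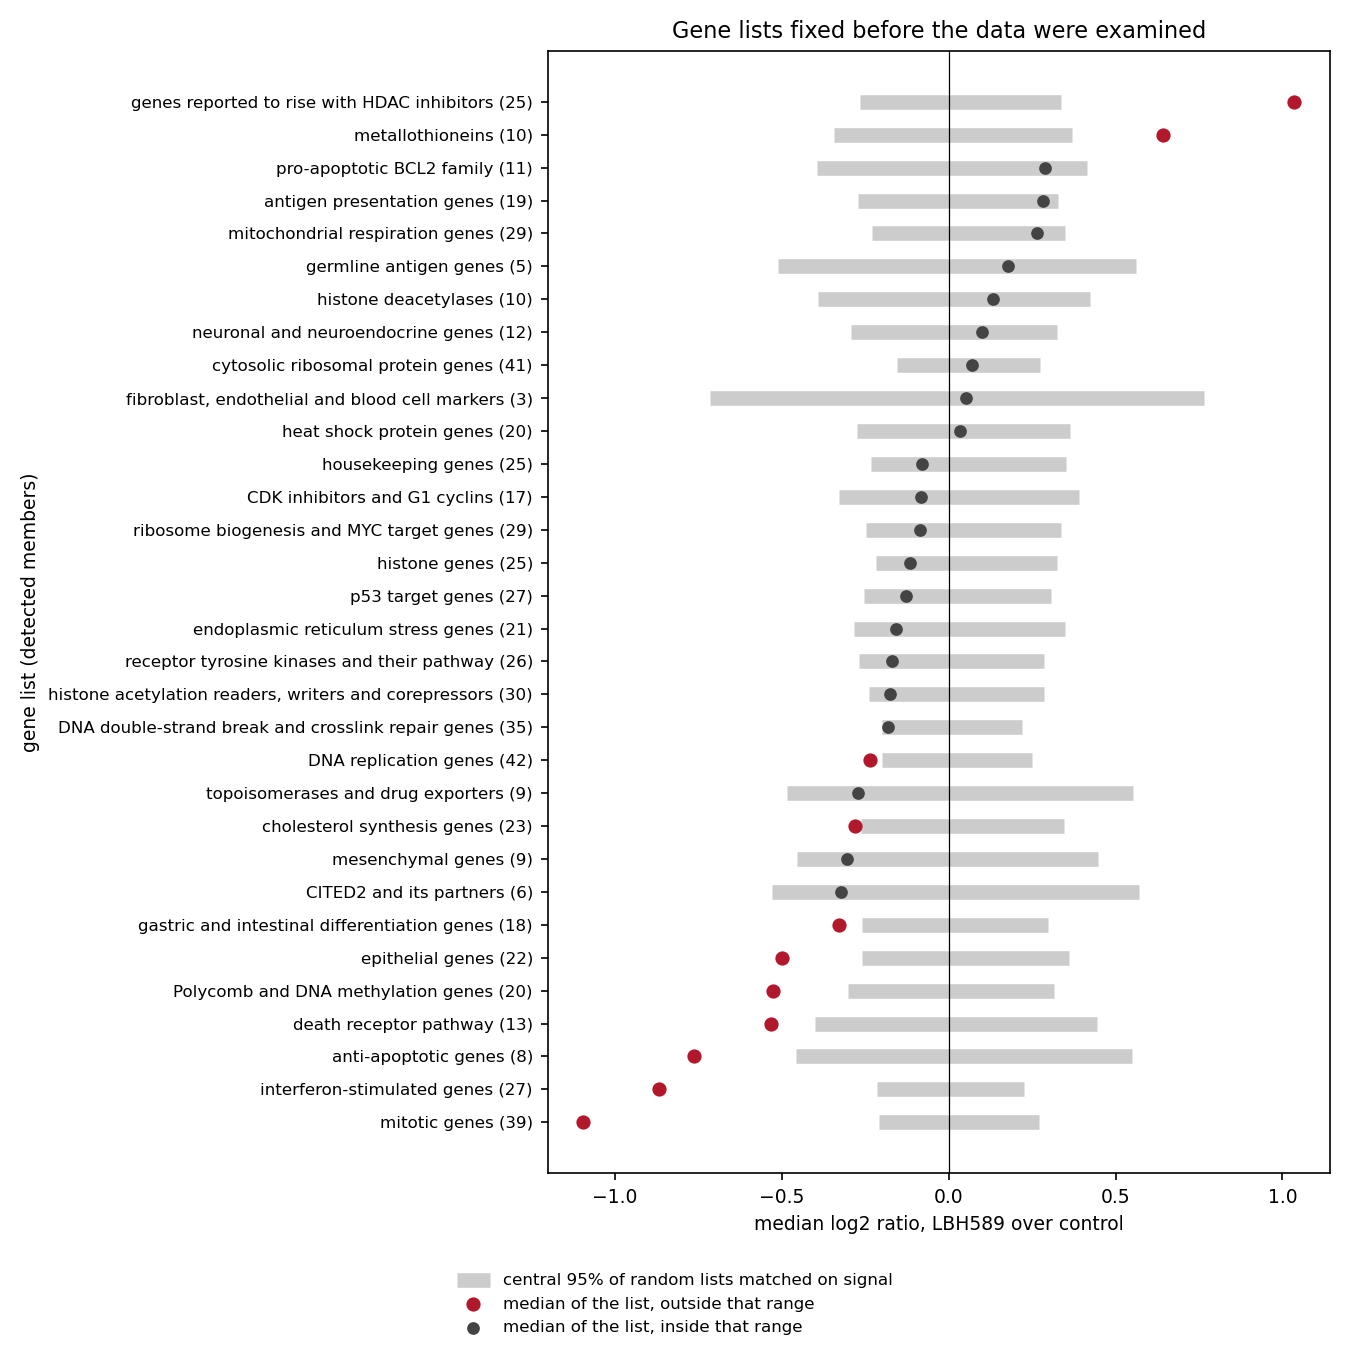
Median log2 ratio of the LBH589 array over the control array (horizontal axis) for each of the 32 gene lists (vertical axis, detected members in brackets). Grey bars are the central 95% of medians of 10000 random lists matched on signal, red points are the 11 medians outside that range and dark points the rest. Mitotic genes lie lowest at -1.09 and genes reported to be higher after histone deacetylase inhibition lie highest at 1.04.

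Mitotic genes were lower on the treated array. Of 39 mitotic genes, 22 were at least 2-fold lower and none higher, with a median log2 ratio of -1.09 at the 0th percentile. MKI67, the proliferation marker Ki-67, was 7.57-fold lower, FOXM1, a transcription factor of the G2 and M phases, was 6.99-fold lower, the kinase gene PLK1 was 6.06-fold lower and the kinesin gene KIF20A was 4.46-fold lower, while CDC25B was 1.15-fold higher. DNA replication genes shifted less, with a median log2 ratio of -0.23 at the 1.13th percentile, 4 of 42 lower and 2 higher. TYMS led them, GINS3 and MCM3, which unwind DNA at the fork as parts of the replicative helicase, were 2.43-fold and 2.25-fold lower, and GINS4 was 4.71-fold higher. This list returned inside the central range with quantile normalization, at the 2.60th percentile, with the offset of 32, at the 4.30th, and above the 75th percentile of signal, at the 8.25th. Of 35 genes of DNA double-strand break and crosslink repair, 5 were lower and 1 higher, with a median of -0.18 at the 3.59th percentile, and of -0.40 above the 75th percentile of signal and -0.043 with the offset of 32, inside the central range under both. RAD51AP1 was 3.77-fold, NBN 2.34-fold and BRIP1 2.27-fold lower, and MRE11 was 2.02-fold higher. Of 9 detected topoisomerases and drug exporters, TOP2A, a target of anthracyclines, was 2.53-fold lower, ABCC1 was 1.48-fold lower, and TOP3B and TDP2 were 1.59-fold and 1.31-fold higher. TOP2B had a log2 ratio of -0.37, and the exporters ABCB1, ABCC2 and ABCG2 were not detected. The median of the list was -0.27 at the 11.5th percentile. It was -0.024 at the 37.15th percentile without a filter and -0.065 with the offset of 32.

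Regulators of the G1 phase did not stand apart. Of 17 detected CDK inhibitors and G1 cyclins, 2 were lower and none higher, with a median log2 ratio of -0.08 at the 25.6th percentile. CDK6 was 2.97-fold and the phosphatase gene CDC25A 2.12-fold lower, RBL1 was 1.53-fold lower and RB1 1.63-fold higher. Of 27 p53 target genes, 6 were lower and 2 higher, with a median of -0.13 at the 13.5th percentile. TP53I3 was 3.59-fold lower and MDM2, the ubiquitin ligase of p53, was 3.43-fold lower. Of 29 genes of ribosome biogenesis and MYC targets, 1 was lower and 1 higher, with a median of -0.09 at the 17.7th percentile. MYC itself was 2.61-fold lower, DKC1 1.99-fold and SRM 1.71-fold lower, and ODC1, the first enzyme of polyamine synthesis, was 5.16-fold higher.

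Genes that restrain or start apoptosis differed in both directions. Of 8 detected anti-apoptotic genes, 3 were at least 2-fold lower and 1 higher, with a median log2 ratio of -0.76 at the 0.10th percentile. BCL2L1, which encodes BCL-XL, was 3.49-fold lower, from 416 to 119, XIAP was 2.60-fold lower and CFLAR, the inhibitor of caspase 8 activation, was at least 2.44-fold lower, while BIRC3 was 6.05-fold higher. Restricted to the 6 members above the 75th percentile of signal, that median was -0.17 at the 25th percentile, and without a filter it was -0.36. The death receptor pathway had a median of -0.53 at the 0.745th percentile, with 4 of 13 lower and 1 higher, and its median was -0.18, at the 2.70th percentile, when undetected members were kept. FAS was 4.37-fold, TNFRSF10A, a receptor of the ligand TRAIL, 3.62-fold and TNFRSF1A 2.44-fold lower, and the kinase gene RIPK1 was 5.11-fold higher. The pro-apoptotic BCL2 family had a median of 0.29 at the 92.1th percentile, with 1 of 11 higher and none lower. BIK was 2.27-fold and BMF 1.74-fold higher, BOK and BID were both 1.78-fold lower, and above the 75th percentile of signal the median of the family was -0.26.

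Genes of epithelial identity were lower on the treated array, and mesenchymal genes differed in both directions. Of 22 epithelial genes, 4 were lower and 1 higher, with a median log2 ratio of -0.50 at the 0.03th percentile. The tight junction gene OCLN was 2.51-fold lower, the splicing regulator ESRP1 was 3.06-fold and the transcription factor GRHL2 2.32-fold lower, while the keratin gene KRT19 was 2.07-fold higher. Gastric and intestinal differentiation genes had a median of -0.33 at the 0.79th percentile, with 4 of 18 lower and none higher. CDH17 and MUC1, an intestinal cadherin and a membrane mucin, were 5.66-fold and 5.58-fold lower, VIL1 was 2.47-fold and CTSE, a gastric aspartic protease, 2.39-fold lower, and SOX2 was 1.58-fold higher. With undetected values set at the detection limit the median of this list was -0.16 at the 11.1th percentile, without a filter it was -0.078 and above the 75th percentile of signal -0.89. Only 9 of the mesenchymal genes were detected, 2 higher and 2 lower, with a median of -0.30 at the 7.37th percentile. TGFB1 was 5.37-fold higher, SNAI1, a repressor of CDH1, was detected on the treated array alone at 14.6 and was at least 3.02-fold higher, and the actin-binding genes TAGLN and CALD1 were 3.20-fold and 3.11-fold lower. The 4 mesenchymal genes above the 75th percentile of signal had a median of -0.94, at the 1.05th percentile. Without a filter the 21 mesenchymal genes had a median of -0.165 at the 0.15th percentile, outside the central range.

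Genes of other lineages remained mostly undetected. Of neuronal and neuroendocrine genes, 12 were detected and 30 were not, 1 was higher and 1 lower, and the median log2 ratio was 0.10 at the 70.6th percentile. SYP, a synaptic vesicle protein, was detected on the treated array alone and was at least 5.79-fold higher. L1CAM was 2.18-fold lower, MAP2 1.85-fold and VGF 1.70-fold higher. Of germline antigen genes, 22 on the array were not detected and the 5 detected were within 2-fold, with a median of 0.18 at the 75.5th percentile. SPA17 was 1.81-fold, CTAG2 1.18-fold and MAGEA6 1.13-fold higher and MAGEA8 1.18-fold lower, and the MAGEA genes share sequence. Of markers of fibroblasts, endothelium and blood cells, which a culture of this line should lack, 3 were detected, none differed by 2-fold and the median was 0.05 at the 50.7th percentile. COL1A1 read 26.6 on the control array and 38.8 on the treated array, and CD68 read 9.23 and 7.90.

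Interferon-stimulated genes, the antiviral program, were lower on the treated array. Of 27 detected members, 13 were at least 2-fold lower and 1 higher, 10 and 1 with undetected values at the detection limit, with a median log2 ratio of -0.87 at the 0th percentile. GBP1, an interferon-induced GTPase, was at least 5.80-fold lower, IFIT2 and IFIT1, which restrict translation of viral RNA, were 5.16-fold and 3.17-fold lower, and OAS1, which senses double-stranded RNA, was 3.26-fold lower. Part of the size rested on members undetected on 1 array. The median was -0.54 with undetected values at the detection limit and -0.42 over members detected on both arrays, at the 0th and 0.35th percentiles. With the offset of 32 it was -0.15, at the 0th percentile. Antigen presentation genes had a median of 0.28 at the 95.3th percentile, with 3 of 19 lower and 1 higher, and of 0.10 with the offset of 32. The peptide transporter gene TAP1 was 3.37-fold, TAPBP 2.83-fold and the immunoproteasome gene PSMB8 2.70-fold lower, while MICA, a ligand of a natural killer cell receptor, was 2.87-fold higher. HLA genes share sequence.

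Genes of Polycomb repression and DNA methylation were lower on the treated array as a list, though 17 of 20 were within 2-fold. They had a median log2 ratio of -0.53 at the 0.10th percentile, with 3 of 20 lower and none higher. None of these 3, TET2, MBD3 and UHRF1, was a Polycomb gene. TET2, a methylcytosine dioxygenase, was 3.88-fold lower, MBD3 2.25-fold, UHRF1 2.01-fold and DNMT1, the maintenance methyltransferase, 1.92-fold lower, while EZH1 was 1.41-fold higher. Above the 75th percentile of signal this list lay at the 3.75th percentile. Histone acetylation readers, writers and corepressors had a median of -0.18 at the 6.65th percentile, with 5 of 30 lower and 1 higher. CHD3 and MTA1, subunits of the NuRD complex, were 3.32-fold and 3.05-fold lower, as was CREBBP by the value above, and the deacetylase gene SIRT2 was 2.89-fold higher. Histone genes went both ways, 4 of 25 higher and 7 lower, with a median of -0.12 at the 11.8th percentile. H4C8 and H2BC8 were 7.20-fold and 3.21-fold higher, H2AC20 and H3C4 were 3.66-fold and 3.08-fold lower, and near-identical copies leave single histone genes uncertain. The 20 histone genes above the 75th percentile of signal had a median of -0.37 at the 1.15th percentile.

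Stress, signalling and metabolic lists completed the set. Of 20 heat shock protein genes, 4 were higher and 1 lower, with a median log2 ratio of 0.03 at the 45.9th percentile. HSPA2 led them, HSPA1A and HSPA1B, near-identical inducible chaperones, were 3.42-fold and 3.18-fold higher, their partner DNAJB1 was 3.23-fold higher and HSPH1 was 2.20-fold lower. Endoplasmic reticulum stress genes had a median of -0.16 at the 10.7th percentile, with 1 of 21 lower and none higher. XBP1, a transcription factor of the unfolded protein response, was 4.57-fold lower, PDIA4 and HERPUD1 were both 1.61-fold lower and SEL1L was 1.79-fold higher. Receptor tyrosine kinases and their pathway had a median of -0.17 at the 9.38th percentile, with 3 of 26 lower and 4 higher. ERBB2, the receptor HER2, was 5.88-fold lower, from 68.7 to 11.7, whereas DUSP1, FOS and EGR1, early response genes, were 8.92-fold, 8.03-fold and 4.23-fold higher. Cholesterol synthesis genes had a median of -0.28 at the 1.85th percentile, with 1 of 23 lower and 2 higher. CYP51A1 was 2.88-fold and ACAT2 1.90-fold lower, INSIG1 and IDI1 were 2.85-fold and 2.36-fold higher, and with the offset of 32 the list lay at the 13.95th percentile. Mitochondrial respiration genes had a median of 0.27 at the 91.3th percentile, with 3 of 29 higher and none lower. NDUFV1 of complex I was 2.76-fold, COX6A1 2.16-fold, COX7B 2.02-fold and SDHD 1.97-fold higher, and CYC1 was 1.44-fold lower.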

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

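All patterns weighed here were picked after their values were seen, and the tests on them were fixed before the values that decide them were computed. Exceptions are the comparison of interferon-stimulated genes with matched random lists, a test chosen after its result was seen, and their medians with a loess trend removed and with the offset. The limit at the 75th percentile was a setting added after the data were seen. One signal lay outside the comparisons of named genes. Among probe sets without any annotation, 1 was not detected on the control array and lay above the 75th percentile of signal on the treated array, at 42.6 against 2.58. The same pattern in the other direction held for 5 probe sets. Of 2843 detected probe sets without annotation, 133 were at least 2-fold higher and 357 at least 2-fold lower on the treated array.

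The interferon-stimulated genes were lower on the treated array. Random lists matched on signal would share a trend of the ratio with signal level. The central 95% of their medians reached down to -0.22 only, against -0.87 for the 27 members. The list stood out by that same comparison, so it adds no independent support. With a loess trend removed from the ratios the median was -0.85 at the 0th percentile, which argues against such a trend as the source. The 12 members above the 75th percentile of signal on at least 1 array had a median of -0.95. This lay at the 0.21th percentile of random lists that passed the same limit. A member could pass on its control signal alone, with a treated value near background. Members detected on both arrays had a smaller median of -0.42, at the 0.35th percentile. The list thus stayed low under both limits, but how much of its size came from noise of dim probe sets was not settled. A difference between the 2 cultures other than the drug, such as cell density, cannot be told apart from an effect of LBH589 with 1 array per group. A lower interferon program after LBH589 therefore may be followed up only as a hypothesis.

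CDKN1A stood at the same level on both arrays, at a log2 ratio of -0.02, although it is a commonly named marker of histone deacetylase inhibition and other genes of that list were much higher. Saturation was argued against, because the brightest probe set exceeded CDKN1A by at least 136-fold on either array. Compression at that signal level was argued against as well, because 19.2% of the 500 genes nearest in mean signal differed by 2-fold (95% Wilson interval 16.0 to 22.9%), against 14.4% of all detected genes. A fault of the gene's single detected probe set, an earlier peak of the transcript and a different behaviour of this line stay open and were not tested, so no more than a candidate explanation can be named.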

How the results depend on the processing

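Of 11 alternatives, 3 could not alter the place of a list among random lists: both centrings shift all genes alike, and the authors' fold equals the ratio of the deposited signals except at the floor. Under the other 8, 28 of 256 list medians moved by more than the spread of random medians, and no list standing apart changed sign. Lists of genes reported to be higher after histone deacetylase inhibition, metallothioneins, mitotic, epithelial and interferon-stimulated genes stood apart under 8 of these 8, the death receptor, gastric, Polycomb, anti-apoptotic and cholesterol lists under 7 and DNA replication under 5. Detection above the 75th percentile, undetected values at the detection limit and leaving out probe sets with the same values were chosen after seeing the data. An offset of 32 by its construction shrinks all ratios, those of dim probe sets most. It left 258 probe sets at least 2-fold higher and 297 probe sets at least 2-fold lower, and 208 genes higher and 224 lower. Under it the list medians were 0.69 for genes reported to be higher after histone deacetylase inhibition, -0.62 for mitotic, -0.073 for DNA replication, -0.043 for double-strand break repair, 0.14 for metallothioneins, -0.25 for anti-apoptotic, -0.25 for death receptor, -0.32 for epithelial, -0.081 for gastric and intestinal, 0.10 for antigen presentation, -0.15 for interferon-stimulated, -0.19 for Polycomb and DNA methylation and -0.067 for cholesterol synthesis genes. A 3-fold size, stricter by construction, left 337 probe sets higher and 442 lower, and 272 genes higher and 326 lower. Without a filter, which adds undetected members at their signal or the floor, the medians were -0.36 for anti-apoptotic, -0.18 for death receptor, -0.078 for gastric and -0.75 for interferon-stimulated genes. Detection on both arrays gave -0.42 for interferon-stimulated genes. Above the 75th percentile of signal, with fewer members, they were -0.40 for double-strand break repair, -0.37 for histone, 3.54 for metallothionein, -0.26 for pro-apoptotic, -0.17 for anti-apoptotic, -0.94 for mesenchymal, -0.89 for gastric and 0.55 for fibroblast, endothelial and blood cell genes. With undetected values at the detection limit they were -0.16 for gastric and -0.54 for interferon-stimulated genes. For histone and mesenchymal genes, inside the central range in the report, detection above the 75th percentile put the list outside it, as did the lack of a filter for mesenchymal genes, and the cause was not tested. Over 168 named genes, 132 values moved by more than the spread between probe sets, 119 of these under the offset, and 1 reversed: H2BC12 stood at 0.029 with the mean of its probe sets. Centring on housekeeping genes made 58.3% of gene calls higher, against 50.2%. Leaving out probe sets by the suffix of their identifier could not be run, since the identifiers carry none. No paired analysis was possible because each group had 1 array. What limits dim genes is their signal over background: a signal near 5 is close to the detection limit of either array.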

Other observations

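The lists described here and the tests on neighbouring genes were chosen after the values were seen, except the count of neighbours that differed in opposite directions. The clearest group not yet described was ciliary. Of 30 detected genes of intraflagellar transport and of the Bardet-Biedl complex, which build and supply the primary cilium, 15 were at least 2-fold higher on the treated array (14 with undetected values at the detection limit) and none lower, with a median log2 ratio of 0.98 and 29 of 30 above 0. BBS9 and WDR19 had log2 ratios of 2.10 and 2.07, IFT80 of 2.03, IFT88 of 1.67 and KIF3A, a subunit of the motor that carries these particles, of 1.67. Mitochondrial genes of acyl-CoA and branched-chain amino acid breakdown were higher too, 12 of 32 by at least 2-fold and none lower, with a median of 0.74. ETFDH, which passes electrons from these reactions to the respiratory chain, went from 10.5 to 111, and GCDH and ACADSB had log2 ratios of 2.60 and 2.59. Both medians were at the 100th percentile of matched random lists, which carries little weight for lists picked from these values.

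Lysosomal genes had a median of 0.29 at the 98.5th percentile, with 9 of 42 at least 2-fold higher and 2 lower. The sialidase gene NEU1 had a log2 ratio of 3.24, from 61.0 to 577, and the channel gene MCOLN1 of 2.10, while GALC and HGSNAT stood at -2.22 and -1.72. Of 28 immediate early genes, 12 were higher (11 with undetected values at the detection limit) and none lower, with a median of 0.79 at the 100th percentile, and CCN1, BTG1 and RHOB had log2 ratios of 2.55, 2.28 and 1.97. Of these 28, 11 belong to lists of the report, and the other 17 had a median of 0.72, 6 of them at least 2-fold higher. All 10 detected desmosome genes had ratios below 0, with a median of -0.66 at the 0.29th percentile. DSC2 went from 160 to 15.3 and DSG2 from 146 to 22.3, and the other 8 were within 2-fold. DSP, JUP and PKP3 belong to the epithelial list as well, and without them the median of the other 7 was -0.34, at the 8.29th percentile, inside the central range.

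A hypothesis was that genes next to each other on a chromosome differed together. Adjacent here means next in order among detected protein-coding genes, so undetected genes were skipped and no limit was set on distance. Of 11712 adjacent pairs among 11735 placed genes, 202 were at least 2-fold apart between arrays in the same direction, 88 higher and 114 lower, where 10000 shuffled gene orders gave 110 to 151 in the central 95%. Pairs 10 genes apart numbered 146, inside their shuffled range of 108 to 149, and adjacent pairs that differed in opposite directions numbered 138, inside 110 to 151, so clustering of changeable genes whatever their direction was argued against. Sequence shared between tandem copies was argued against as the whole source by 177 pairs whose symbols do not share their first 3 letters, above 104 to 144. Shared position may play a part, but neighbours of related function were not set apart from other pairs. Such neighbours include the histone genes H3C2 and H2AC4 and the interferon-stimulated genes IFIT2 and IFIT3. Overlapping or read-through transcripts stay open as well, and the link was weak over all genes. At the distances of 1 to 20 genes tried first, Spearman's rho across pairs ran from 0.0032 to 0.024.

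Examples of such pairs are DTX3L beside PARP9 and PARP14, with log2 ratios of -3.11, -2.63 and -3.13, LGR5 beside TSPAN8, with -2.98 and -2.43, ERAP2 beside ERAP1, with -3.25 and -1.98, and POLR3GL beside TXNIP, with 1.24 and 6.03. ERAP1 and ERAP2 share the first 3 letters of their symbols. Whether position, shared regulation or shared sequence lay behind any single pair was not tested.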
